A study of Oryza sativa with 8 samples.

How the data were processed

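Gene expression was measured in whole roots of rice seedlings (cultivar Koshihikari) on 8 one-colour oligonucleotide arrays, 1 per RNA sample. Per the labels, the plants grew for 10 days in 0.005 mM or in 1 mM ammonium chloride, with 4 biological replicates at each concentration. The labels name Cy3 as the dye.

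The deposited array files hold spot intensity on a linear scale, written by Agilent Feature Extraction 10.10.1.1 per the file headers. The processed signal in them is already background-corrected by that software, and the files also carry flags for spots that are well above background, saturated or outlying. The authors' deposited table lists features with a p-value, a q-value and a log2 ratio of the average it calls nitrogen sufficient over the average it calls deficient, read here as 1 mM and 0.005 mM. Its 8 columns of scaled signals per array were not used, because their names do not match the sample titles.

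Log2 of the processed signal was taken, and the 75th percentile over non-control spots of the same array was subtracted. Control spots and spots with an outlier flag were left out, and spots of 1 probe were averaged. A probe was kept where it was well above background on at least 4 of the 8 arrays. The array's probe names give rice RAP locus identifiers. The kept probe with the highest mean signal stood for its locus, and a probe without a locus stood for itself. This left 24969 units, of which 24776 were loci and 182 were probes named for microRNAs. Of the 7016 loci with several kept probes, 143 had probes called in opposite directions.

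The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all 24969 units and a threshold of 0.05. Changes are given as 1 mM minus 0.005 mM. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 7 lists with at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. Where a probe was well above background on no array of a group, its fold is a lower bound, set against the lowest signal well above background on each array of that group.

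No file or table used here pairs the RAP loci with gene names or descriptions. The 25 gene lists were fixed before the data were examined, partly as text searches of descriptions, which could not be run, and partly as 72 pairs of a locus and a symbol written from general knowledge. The pairs were checked against the symbols in a RefSeq gene table (assembly ASM3414082v1), which holds no RAP loci. A pair passed if the table placed the symbol on the chromosome that the locus identifier names, within 2 Mb of the position interpolated from other pairs. The table held the symbol of 56 pairs. It contradicted 3, listed as TOM1 and IRO2 for iron acquisition and RR10 for cytokinin. These 3 were left out, and 53 passed. The other 16 stayed in their lists without a printed name. A further 284 pairs, written after the files had been seen, served only to interpolate positions and entered no list, test or name. Over all pairs that could be checked 96.7% passed, against a mean of 1.88% when positions were shuffled among pairs. The check cannot tell neighbouring genes apart, and the link from locus to symbol itself was read from no table. Only 12 of the 25 lists held a usable locus. The others rested on descriptions alone and were not assessed. Lists of markers for green tissue and for seed were among these, so other tissues in the samples were not assessed.

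The rule for named genes, fixed before the data were examined, had 3 parts. The first, the 10 largest increases and decreases among genes with a description, could not be applied without descriptions. In its place the 2 loci with the largest fitted increase and the 2 with the largest fitted decrease are given, among those with groups that did not overlap and a signal well above background on all 4 arrays of the brighter group. The second takes every measured ammonium transporter and ammonium assimilation enzyme, here those with a printed name. The third takes up to 4 members past the threshold with the largest change from each other list, here among members with a printed name. IRT1, PT2 and PT6 were named in addition, after their values had been seen.

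The functions were tested on simulated data for this comparison, with 24969 units of the real means and spreads. Of 50 genes changed by each size, 4 were recovered at a log2 change of 0.25, 32 at 0.5, 43 at 1 and 49 at 2. Of the calls, 1.47% were unchanged genes. Nearly all simulated units were left unchanged, whereas 76.07% of the real units were called. The adjustment is stricter where few units change, so these rates do not carry over to the real comparison. Scaling between arrays was not tested with many units changed.

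Alternatives covered the scaling between arrays, the background correction, the filter, the unit, a block on replicate number, array weights, the variance model, the test and each replicate left out. Normexp was run on the median spot signal, since the files hold no mean signal, and was followed by quantile normalization, so that setting changed both steps together. Scaling by spike-in probes was added after seeing the data. The 4 arrays of 0.005 mM were on 1 slide and the 4 of 1 mM on another, so slide and group cannot be told apart, and a slide block could not be fitted. The number of arrays limits the precision.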

Results

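The series compared roots of rice seedlings grown at a low and at a higher supply of ammonium, the form of nitrogen that rice in flooded soil mainly takes up, and addressed how root gene expression responds to it. The ammonium chloride concentration was 0.005 mM for 4 arrays and 1 mM for the other 4. Between 81.4% and 85.1% of the non-control spots on an array were well above background, and no such spot was saturated. Correlations across genes ranged from 0.9925 to 0.9966 between arrays of the same group and from 0.9242 to 0.9344 between groups. Log2 changes below are 1 mM minus 0.005 mM ± SE from limma with n = 4 per group, and levels are log2 signals relative to the array's 75th percentile.

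At 1 mM ammonium, all 7 measured members of the list of nitrate uptake and reduction fell. In the list of ammonium transporters 6 of 9 fell and 3 rose, and in that of iron acquisition 5 of 7 rose. Of these lists, only that of nitrate genes passed camera at the preset correlation. Here and below, counts per pathway cover list members only, and the array holds further genes of such pathways. Among the listed genes the nicotianamine synthase genes NAS2 and NAS1 rose by the largest amounts. Of 24969 units tested, 8065 (32.3%) were higher and 10930 (43.77%) were lower in 1 mM at an adjusted p under 0.05 (limma). At least 2-fold changes were found for 2462 higher and 2161 lower units. This order turned with scaling, to 1835 higher and 3485 lower without scaling between arrays and 1700 and 4119 with spike-in scaling. The values of both groups did not overlap for 71.6% of units, against 2.857% by chance. The split of calls depended on scaling: higher calls were 42.5% of all calls here, 24.9% without scaling between arrays and 20.9% with spike-in scaling, where the median change was -0.44 in place of -0.086. Each group had its own slide, so slide and ammonium supply cannot be told apart in any of these comparisons.

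All 7 measured members of the list of nitrate uptake and reduction fell, adjusted over all genes as well as adjusted over the list alone. The high-affinity nitrate transporter genes NRT2.1 (Os02g0112100), NRT2.2 (Os02g0112600) and NRT2.3 (Os01g0704100) changed by -7.96 ± 0.25, -3.30 ± 0.16 and -5.25 ± 0.06. NRT2.3 went from 5.84 ± 0.11 (SD, n = 4) to 0.59 ± 0.06, and the nitrate reductase gene NIA1 (Os08g0468100) changed by -3.74 ± 0.26. NRT2.1 and NRT2.2 are close copies, so their probes may share signal. The list passed the threshold with camera (adjusted p = 0.00309), but not with an estimated correlation (adjusted p = 0.455).

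Of the 9 ammonium transporter genes, 6 fell and 3 rose, with the same counts adjusted over the list alone. AMT3;3 (Os02g0550800) fell the most, by -3.66 ± 0.07, from -0.18 ± 0.02 to -3.84 ± 0.15. AMT3;2 (Os03g0838400), AMT3;1 (Os01g0870300), AMT2;1 (Os05g0468700) and AMT1;1 (Os04g0509600) changed by -1.79 ± 0.07, -1.62 ± 0.06, -0.85 ± 0.06 and -0.85 ± 0.04. AMT2;3 (Os01g0831300) rose by 3.91 ± 0.24 and AMT2;2 (Os01g0831900) by 0.53 ± 0.10, the latter not past the threshold with spike-in scaling. The neighbouring loci Os02g0620500 and Os02g0620600 moved apart, at -2.62 ± 0.10 and 0.66 ± 0.07. They were listed as AMT1;2 and AMT1;3, but the gene table orders these symbols the other way round, so which is which was not settled. As a group the list did not pass camera (adjusted p = 0.207).

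**Figure D1:**
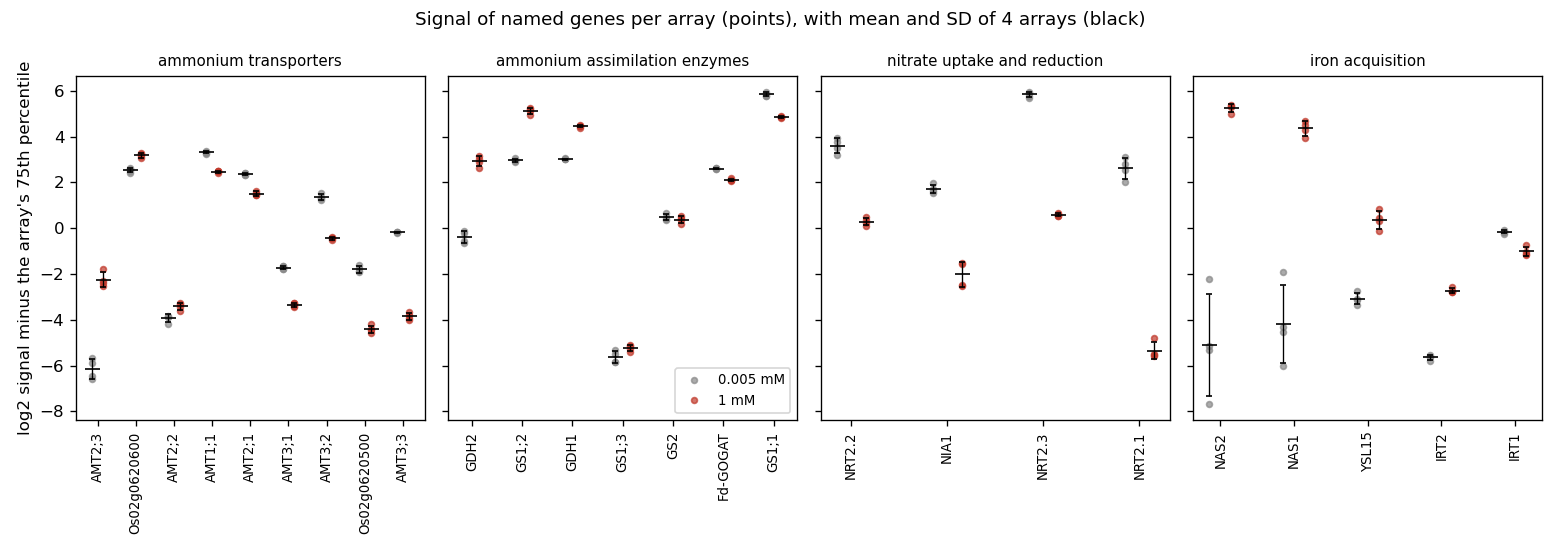
Log2 signal relative to the array's 75th percentile (vertical axis) of named genes in 4 lists (horizontal axis), for 4 arrays at 0.005 mM (grey) and 4 at 1 mM (red), with the mean and SD in black. The named nitrate genes lie lower at 1 mM, and NAS2 goes from a mean of -5.10 to 5.25.

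Of the 11 genes of ammonium assimilation, 7 rose, 3 fell and 1 did not pass, also when adjusted over the list alone. The glutamine synthetase genes, whose products join ammonium to glutamate, moved in different directions. GS1;2 (Os03g0223400) rose by 2.16 ± 0.07, from 2.96 ± 0.07 to 5.12 ± 0.13, while GS1;1 (Os02g0735200) changed by -0.99 ± 0.05. GS1;3 (Os03g0712800) was at 0.41 ± 0.13 (limma adjusted p = 0.0228), a call that ended without scaling, with spike-in scaling and without any of 4 single arrays. GS2 (Os04g0659100) had a value of -0.10 ± 0.09 (limma adjusted p = 0.333), while 3 of its 4 kept probes were called higher, and its call went both ways between settings. The glutamate dehydrogenase genes GDH2 (Os04g0543900) and GDH1 (Os03g0794500) rose by 3.31 ± 0.15 and 1.43 ± 0.04, and Fd-GOGAT (Os07g0658400), a glutamate synthase gene, changed by -0.48 ± 0.04. Spike-in scaling moved the median of all units by -0.35, more than the 0.30 ± 0.09 of 1 unnamed member among those that rose. The list did not pass camera (adjusted p = 0.151).

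Of the 7 measured iron acquisition genes, 5 rose, 1 fell and 1 did not pass, also when adjusted over the list alone. NAS2 (Os03g0307200) and NAS1 (Os03g0307300), which encode nicotianamine synthases, rose by 10.35 ± 0.97 and 8.56 ± 0.76. Their levels at 0.005 mM varied widely, with SDs of 2.23 and 1.71 (n = 4), NAS2 was well above background on 3 of those 4 arrays, and the genes are close copies whose probes may share signal. The changes were 11.30 and 9.33 without replicate 2 at 0.005 mM, and 9.49 and 7.95 without replicate 4. The genes for the iron transporters YSL15 (Os02g0650300) and IRT2 (Os03g0667300) rose by 3.44 ± 0.20 and 2.92 ± 0.08. IRT1 (Os03g0667500), an iron transporter gene named after its value had been seen, was the member that fell, at -0.86 ± 0.09. The list missed the threshold with camera (adjusted p = 0.0624).

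Of the 7 measured genes of the phosphate starvation response, 3 rose, 3 fell and 1 did not pass by the probe that stands for each, also when adjusted over the list alone. Probes of a gene disagreed here: PT2 (Os03g0150800) counts as fallen at -0.38 ± 0.07 while 7 of its 8 kept probes were called higher, and PT6 (Os08g0564000) as not passed at 0.03 ± 0.12 while its other probe was called lower. With the mean of a gene's probes, PT2 was called higher at 1.37 and PT6 lower at -1.05. The phosphate transporter genes PT8 (Os10g0444700) and PT4 (Os04g0186400) rose by 2.16 ± 0.16 and 1.75 ± 0.08. SPX3 (Os10g0392600) rose by 0.97 ± 0.18 (0.32 with normexp and quantile normalization), and SPX2 (Os02g0202200) changed by -1.14 ± 0.07. The list did not pass camera (adjusted p = 0.897).

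Of the 6 cytokinin genes measured, 2 rose, 3 fell and 1 did not pass, also when adjusted over the list alone. The response regulator genes RR1 (Os04g0442300) and RR4 (Os01g0952500) rose by 1.01 ± 0.13 and 0.45 ± 0.09, the latter not past the threshold without scaling or with spike-in scaling. RR6 (Os04g0673300) and RR9 (Os11g0143300) changed by -0.77 ± 0.10 and -0.47 ± 0.13. Of the 6 terpenoid phytoalexin genes measured, 2 rose and 4 fell, also when adjusted over the list alone. The diterpene synthase gene KSL4 (Os04g0179200) and CYP99A2 (Os04g0180400) rose by 2.03 ± 0.22 and 1.29 ± 0.18, whereas KSL7 (Os02g0570400) and CYP99A3 (Os04g0178400) changed by -1.62 ± 0.40 and -0.84 ± 0.10. KSL7 was well above background on 2 of the 4 arrays at 1 mM, and its change was -0.40 with normexp and quantile normalization. Camera gave adjusted p = 0.967 for the cytokinin list and adjusted p = 0.928 for the terpenoid list.

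In lists with too few measured genes for a set test, the urea transporter gene DUR3 (Os10g0580400) changed by -2.07 ± 0.08. The potassium transport genes AKT1 (Os01g0648000) and HAK1 (Os04g0401700) changed by -1.25 ± 0.07 and -0.90 ± 0.07, while the third member did not pass. All 3 measured members of the strigolactone synthesis list fell, among them D17 (Os04g0550600) at -1.21 ± 0.09. The only measured member of the sulfate list rose and the only measured member of the organic acid supply list fell. The array holds further genes of these pathways, which were in no list and were not assessed.

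By fitted change, Os10g0454700 and NAS2 stood first among loci that rose, with Os10g0454700 at 11.40 ± 0.46, and NRT2.1 and Os01g0700500 among loci that fell. The probe of Os10g0454700 was well above background on 1 of the 4 arrays at 0.005 mM. Os01g0700500 was at least 50.6-fold lower in 1 mM, where its probe was not well above background on any array. With signals this near background, neither the order of these loci nor the size of the change of Os10g0454700 is settled. Neither Os10g0454700 nor Os01g0700500 has a name in the sources used here.

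The signal of the arrays relative to added control RNA differed between the groups. The array's 75th percentile was set against the mean of 7 spike-in probes. It lay at -0.65 ± 0.05 (SD, n = 4) log2 units at 0.005 mM and at -1.03 ± 0.11 at 1 mM. The difference was -0.38 (two-sided exact permutation p = 0.0286, the smallest this design allows). Each group had 1 slide, so the test rests on the spread among arrays of a slide and does not cover differences between slides.

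**Figure D2:**
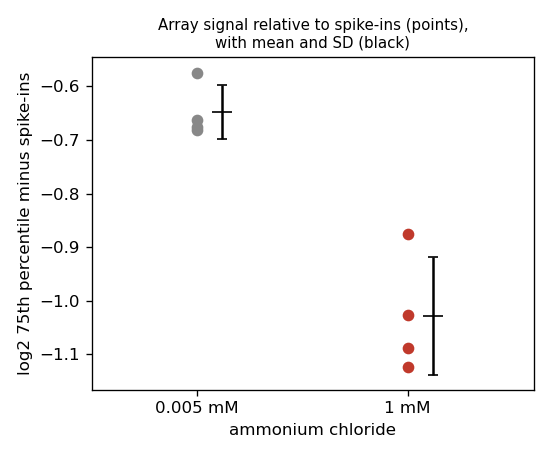
Log2 of the array's 75th percentile minus the mean log2 of 7 spike-in probes (vertical axis) for the 4 arrays of each ammonium chloride concentration (horizontal axis), with the mean and SD in black. All 4 arrays at 1 mM lie below all 4 at 0.005 mM.

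The authors' deposited table lists 28381 features, of which 9524 are higher and 18857 lower in the group it calls nitrogen sufficient, read here as 1 mM. Listed features are spots, 64.89% of the non-control spots, and all have a q-value under 0.05 (largest 0.04998). Being listed is thus a call by the authors' own test. Of the units tested here, 19304 were listed in the authors' deposited table, of which 17068 were also called here and 2236 were not, and 1927 were called here but not listed in the authors' deposited table. Of the 17068, 17062 had the same direction in the authors' deposited table. Direction was thus compared only among units called in both.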

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

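All tests of explanations in this part were chosen after the result was seen. In 94 groups of 4 array values, 5 had 1 array whose gap to the nearest other, over the group's range, passed Dixon's critical value for 4 values, and chance gives about 1 in 20. NRT2.1 at 1 mM was -4.81 in replicate 4 against -5.57 to -5.48 in the others (ratio 0.886). AMT1;1 at 1 mM was 2.4 in replicate 4 against 2.48 to 2.49 (ratio 0.859). GDH1 at 0.005 mM was 3.05 in replicate 2 against 3.0 to 3.01 (ratio 0.87). CYP99A3 at 0.005 mM was 1.33 in replicate 1 against 1.13 to 1.16 (ratio 0.875). PT6 at 0.005 mM was -2.71 in replicate 1 against -3.09 to -3.05 (ratio 0.888). Of 11 control probes designed on plants other than rice, 2 were well above background on all 8 arrays, a signal that entered no comparison.

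The groups differed in 18995 of 24969 units. Among the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many, and the highest of the others gave 0. The other splits mix arrays of both groups, which raises the spread within each, so their low counts follow from the separation itself. A share of 1 in 35 is the lowest these splits allow, so they cannot exclude chance. The differences of the 7 bright spike-in probes between slides lay within 0.0258 log2 units of their mean, so no probe-specific difference of slide or scan was seen in them. They are few and were added after growth and RNA extraction, and each group had 1 slide. A difference in slide, growth or extraction therefore cannot be told apart from ammonium supply.

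Lower calls outnumbered higher calls. Under the 6 scalings run, higher calls were at most 44.1% of all calls. This does not decide whether scaling is the cause, because 4 of the 6 centre or equalise the arrays and so largely fix the balance. The others gave 24.9% without scaling and 20.9% with spike-ins, and at 2-fold the direction turned, with 2462 higher and 2161 lower in the main setting against 1700 and 4119 with spike-ins. Scaling, ammonium supply and slide stay open.

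NAS2 and NAS1 spread widely at 0.005 mM. Leaving out replicate 2 lowered the SD the most, to 1.42 from 2.23 for NAS2 and to 0.93 from 1.71 for NAS1. Leaving out replicate 4, at the other extreme, lowered it to 1.73 for NAS2 and 1.47 for NAS1. Removing an extreme value lowers an SD in any case, so the drop does not single out replicate 2. What remained argues against 1 aberrant array as the whole cause. No biological explanation was tested.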

How the results depend on the processing

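Spike-in scaling was chosen after seeing the data; the other alternatives were planned. Units higher in 1 mM numbered 4882 without scaling, 12158 with every probe as a unit (more units tested) and 4085 with spike-in scaling, against 8065. Units at least 2-fold lower numbered 3485 without scaling and 4119 with spike-in scaling, against 2161. Of the fixed lists, 1 of the 7 tested passed the threshold in the main setting. The number was 3 without scaling, with the mean of probes and with spike-in scaling. It was 2 with quantile normalization, with normexp and quantile normalization together or with no filter, and 4 with every probe. Camera with an estimated correlation gave 0. Fry, which does not compare a list with other genes, gave 5. GS2, not called in the main setting, was called higher at 0.81 with normexp and quantile normalization and at 0.66 with the mean of its probes, but lower at -0.38 without scaling and at -0.46 with spike-in scaling. With the mean of probes PT2 reversed to 1.37 and PT6, otherwise not called, was called lower at -1.05. PT6 was -0.24 without scaling, -0.33 with spike-in scaling and -0.053 to 0.12 without 1 array. The causes were not tested. Leaving out 1 array gave 7534 to 7896 higher, 10342 to 10943 lower, 2238 to 2486 at least 2-fold higher, 2008 to 2227 at least 2-fold lower, and 1 to 2 lists. Of 43 named genes, 37 kept their direction and side of the threshold under every alternative that kept them; the others were GS1;3, GS2, RR4, AMT2;2, PT2 and PT6. Asking for all 8 arrays above background dropped NAS2 and KSL7. The fold moved by over 1.5 times for 9 named genes with normexp and quantile normalization. Besides GS2, KSL7 and SPX3, log2 changes became 3.0 for AMT2;3, 2.1 for IRT2 and 1.38 for KSL4. They became -7.3 for NRT2.1, 9.14 for NAS2 and 7.87 for NAS1. The fold also moved with the mean of probes for GS2, PT2, PT6 and PT4 (log2 change 1.16). With arrayWeights it moved for NAS2 (log2 change 9.7).

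With the replicate block, 8115 units were higher and 10993 lower. Deviations of same-numbered samples correlated at 0.32, -0.01, 0.10 and 0.08, against at most 0.1 for different numbers, and in 2 of the 4 numbers both samples correlated best with each other. Not every pair was over 0.1, so the numbers were not taken as pairs, and a structure shared by some of them stays open. The slide block and random slide block were not run, as each group has its own slide.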

Other observations

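Probes named for microRNAs were mostly dim. They were identified by name alone and were not taken to measure the mature microRNA. Of 510 such probes, 182 were tested, 40 were higher and 63 lower in 1 mM, and 19 and 39 of these changed at least 2-fold. Over all units tested, 32.3% were higher and 43.77% were lower.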
